A study of Rattus norvegicus with 115 samples.

How the data were processed

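The authors isolated RNA with the mirVana kit and labelled 200 ng of total RNA with biotin using the 3' IVT Express kit, per the labels' protocols. Per the submitters' processing notes, the arrays were processed in Affymetrix Expression Console with MAS5 and RMA, and for the BB samples with RMA alone, with no versions given. The deposited values are intensity, normalized by the authors and rounded to whole numbers from 7 to 27837, and the array medians ran from 117 to 165. The design had assumed log2 values, so log2 was taken here. At the lowest intensity the rounding is a step of 0.19 log2, and at the lower quartile, 37, a step of 0.038.

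Of 31099 probe sets, 57 control probe sets, 436 with several gene symbols and 9780 with none were left out. The other 20826 gave 14217 genes. Of these, 4525 had more than 1 probe set and were represented by the one brightest on average over all arrays. Among genes called in MRT contralateral samples at 48 h, 1367 had other probe sets, and in 169 of them another probe set was called in the opposite direction.

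Groups, comparisons, tests, gene lists and the first set of alternatives were chosen before the data were examined. Group means were fitted per tissue, or over all 115 arrays for comparisons between tissues, with limma 3.58.1 in R 4.3.3, with empirical Bayes variances that follow intensity and Benjamini-Hochberg adjustment over all genes. A gene was called at adjusted p under 0.05, and 33 comparisons were fitted. The 13 pathway lists and 16 marker lists held 567 genes, of which 490 were measured. They were tested with camera, and the mean of each list per array was compared by exact permutation, a test added after seeing the data. Other tools were data.table (1.17.8), Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

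Named genes were drawn by rule. For each comparison within a tissue the rule picks the 8 largest rises and the 8 largest falls among called genes whose groups did not overlap, and, for each list called by camera, the 3 called members with the largest moderated statistic in its direction. A list without a call names at most 3 members, those of the largest absolute statistic. Not all genes so picked are named.

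The rat number is given for each sample by the labels, and 55 of the 60 rats have both tissues. Of these 55, 38 had a correlation over 0.1 between the deviations of the tissues from their group means. The median was 0.186 for the same rat and -0.0435 for other rats of the same group. So the rat pairs the samples. The main comparisons between tissues treat the arrays as independent, as fixed beforehand, and the rat as a replicate block, with a consensus correlation of 0.157, was run as an alternative. Other alternatives changed the normalization, the genes kept, the probe set per gene, the variance prior, the array weights, the groups fitted, a covariate or the arrays kept, single arrays only in groups of 5 or fewer.

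The fit was tested on simulated data with 50 of 14217 genes changed at each of 4 sizes. For MRT against untreated tumours at 6 h, 64, 78, 98 and 100 percent of changes of 0.5, 1, 2 and 3 log2 were recovered, with 8 false calls among 178. At 8 d the shares were 26, 78, 96 and 100 percent, with 9 of 159 calls false. MRT against BB tumours at 15 d gave 22, 70, 92 and 100 percent, with 8 of 150 false. Contralateral MRT against untreated at 6 h gave 66, 94, 98 and 100 percent and 11 of 190 false. Data without a change gave at most 1 call, and camera called the 1 list that was shifted and 0 others. These rates hold for the simulated data alone. In the arrays, 56 of 374 list calls held with an estimated correlation, and some other divisions of the samples gave many calls, as given below.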

Results

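Gene expression was measured on 115 arrays from 9L tumours implanted in rat brain (59 arrays) and from the opposite hemisphere (56 arrays) of 60 rats. The rats were untreated, or received microbeam radiation (MRT, 400 Gy in the microbeams and 18 Gy in the valleys) or a broad beam (BB, 17.4 Gy), and tissue was taken at 6 h, 48 h, 8 d or 15 d. Untreated tumours numbered 5, 4 and 4 at 6 h, 48 h and 8 d, MRT tumours 9, 8, 7 and 4 and BB tumours 6, 4, 4 and 4 up to 15 d. Contralateral samples numbered 5, 4 and 4 untreated, 9, 7, 6 and 4 after MRT and 6, 3, 4 and 4 after BB, and no untreated sample was taken at 15 d. All 35 BB arrays carry their own label set, so within a tissue an effect of BB and a difference between label sets cannot be told apart. After expression was taken to log2, limma compared 14217 genes, and changes are given as log2 difference ± standard error; a gene was called at adjusted p under 0.05. Unless stated, rises and falls are against untreated samples of that time, which also differed between times. Those given as largest are so among called genes whose groups did not overlap. Gene lists fixed beforehand were tested with camera at a preset correlation of 0.01, and 56 of 374 list calls held with an estimated correlation; a list given without a camera value was not called or lost its call with that correlation. Array quality weights changed 26 of the 33 counts by more than 1.5 times, mostly upward, and are not repeated below.

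Untreated tumours differed from the opposite hemisphere in most genes. All 27 mitosis genes were higher in tumour (median 4.19, 27 adjusted over the list alone), among them Cdk1 (5.21 ± 0.25), Ccnb2 (4.92 ± 0.24) and Ube2c (5.21 ± 0.26), as were all 26 DNA replication genes (median 2.65, 26 adjusted over the list alone), among them Mcm6 (4.06 ± 0.21). Matrix genes were higher in 22 of 24 cases (median 3.99, 23 adjusted over the list alone). Among them were Timp1 (4.97 ± 0.22) and Col5a2 (5.01 ± 0.24). All 20 antigen presentation genes were higher (median 2.08, 20 adjusted over the list alone), among them the immunoproteasome subunit Psmb8 (3.57 ± 0.17). Among single genes Spp1 (5.33 ± 0.26) and Mmp3 (6.94 ± 0.39), a secreted phosphoprotein and a matrix protease, the cell-cycle inhibitor Cdkn2a (6.28 ± 0.33) and Gbp2 (4.41 ± 0.21) stood high. Neuron markers were lower in 19 of 23 cases (median -1.87, 19 adjusted over the list alone). Among them were the receptor subunit Grin1 (-2.03 ± 0.21) and the synaptic vesicle gene Syp (-1.95 ± 0.22). Limma called 11526 genes (5753 higher, 5773 lower) between 13 tumour and 13 contralateral arrays, 4092 of them past 1 log2, and 4301 higher and 7759 lower after the arrays were shifted to a common median.

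Untreated tumours also changed as they grew from the 6 h to the 8 d time point. The largest rises were the B-cell chemokine Cxcl13 (4.18 ± 0.69), the hypoxia-induced carbonic anhydrase Car9 (3.55 ± 0.40), the stress regulator Ddit4 (3.10 ± 0.29) and the microfibril gene Mfap2 (3.02 ± 0.45). The largest falls were genes of striatal and other neurons, Scn4b (-3.49 ± 0.73), Pcp4 (-3.33 ± 0.66), Nefm (-3.25 ± 0.60), Esrrg (-3.15 ± 0.68) and Tac1 (-3.09 ± 1.11). Neuron markers averaged 10.18 ± 0.43 at 6 h, 10.27 ± 0.87 at 48 h and 8.09 ± 0.56 at 8 d, and 19 of 23 fell (median -2.18, 20 adjusted over the list alone). Hypoxia genes rose in 17 of 22 cases (median 0.94, 17 adjusted over the list alone, camera adjusted p = 1.1e-10). Among them were Ndrg1 (1.74 ± 0.21) and Kdm3a (1.12 ± 0.15). T and NK cell genes rose in 11 of 24 (median 1.04, 17 adjusted over the list alone). Among them were Ccl5 (2.01 ± 0.37), Cd8a (2.16 ± 0.47) and Prf1 (1.95 ± 0.44). Limma called 4151 genes (2275 higher, 1876 lower) (n = 4 and 5), with a median of all genes of 0.11; with the neuron markers as a covariate 233 genes were called, of which 152 were among the 4151. Among the 14 genes named, 1 lost the call when some array was left out, and Tac1 reached adjusted p = 0.079 without untreated 8 d rat 27.

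At 6 h after MRT, tumours (n = 9 and 5) had raised transcripts of inflammation and of p53 target genes. Rises were largest for the lipase regulator Angptl4 (2.76 ± 0.32), the endothelial adhesion molecule Sele (2.61 ± 0.35), the cyclin-dependent kinase inhibitor Cdkn1a (2.53 ± 0.20), the prostaglandin synthase Ptges (2.36 ± 0.26) and the protease inhibitor Tfpi2 (2.25 ± 0.35). Falls were largest for the Golgi protein Golm1 (-1.74 ± 0.30), the tetraspanin Tspan8 (-1.32 ± 0.31) and the myeloid receptor Trem2 (-1.06 ± 0.24). Cytokine and adhesion genes rose in 13 of 20 cases (median 1.45, 15 adjusted over the list alone, camera adjusted p = 1.9e-33). They included the chemokines Ccl2 (2.86 ± 0.37) and Ccl3 (2.45 ± 0.35). Targets of p53 rose in 11 of 25 (median 0.34, 14 adjusted over the list alone, camera adjusted p = 1.0e-28). Among them were Aen (1.40 ± 0.12) and Mdm2 (1.12 ± 0.12). Neutrophil genes rose in 4 of 10 (median 0.87, 6 adjusted over the list alone, camera adjusted p = 1.1e-12). Among them were S100a9 (3.10 ± 0.57), S100a8 (2.25 ± 0.44) and Lcn2 (1.29 ± 0.26). Reactive astrocyte genes rose in 4 of 14 (median 0.57, 7 adjusted over the list alone, camera adjusted p = 4.1e-09). Among them was Steap4 (2.59 ± 0.51). Glucocorticoid targets rose in 3 of 15 (median 0.41, 4 adjusted over the list alone, camera adjusted p = 1.4e-05). Among them were Errfi1 (1.00 ± 0.18) and Nfkbia (0.92 ± 0.22). Interferon-response genes rose in 6 of 31 (median 0.54, 13 adjusted over the list alone). Among them were the antiviral Rsad2 (2.43 ± 0.39) and the chemokines Cxcl10 (2.48 ± 0.45) and Cxcl11 (2.90 ± 0.55). The immediate early genes Atf3 (1.83 ± 0.28) and Fos (1.25 ± 0.30) rose. Mitosis genes fell in 7 of 27 cases (median -0.95, 18 adjusted over the list alone). They included the cell-division genes Cdc20 (-2.09 ± 0.39), Plk1 (-1.44 ± 0.31) and Aurka (-1.44 ± 0.33). Microglia markers fell in 4 of 8 (median -0.71, 4 adjusted over the list alone, camera adjusted p = 3.3e-09). Among them were P2ry12 (-2.66 ± 0.39) and Gpr34 (-1.85 ± 0.39). Endothelial genes fell in 4 of 20 (median -0.52, 12 adjusted over the list alone, camera adjusted p = 1.3e-08). Among them were Tek (-0.89 ± 0.19), Sox18 (-0.70 ± 0.18) and Emcn (-0.71 ± 0.19). Neuron markers had a median change of -0.05. Limma called 202 genes (144 higher, 58 lower), 70 with only these groups in the fit and 362 with the neuron markers as a covariate. The count was 131 and 131 without untreated rats 1 and 3 in turn. With 1 array left out, 7 of these 31 genes lost the call, and Sox18 reached adjusted p = 0.16 without untreated rat 3.

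By 48 h (n = 8 and 4) the tumours had gained myeloid transcripts. The largest rises were the DNA repair enzyme Mgmt (3.13 ± 0.35), the T-cell coreceptor Cd8a (2.98 ± 0.43), the leukocyte receptors Lilrb4 (2.65 ± 0.55) and Cd300c2 (2.56 ± 0.38), the epoxide hydrolase Ephx1 (2.57 ± 0.42) and the matrix protease Mmp10 (2.52 ± 0.55). The largest falls included the growth factor Bmp4 (-1.41 ± 0.33), the collagen Col11a2 (-1.02 ± 0.22), the imprinted RNA H19 (-0.86 ± 0.20) and the sterol gene Acat2 (-0.95 ± 0.22). Cholesterol synthesis genes fell in 7 of 17 cases (median -0.59, 13 adjusted over the list alone, camera adjusted p = 2.9e-14). Among them were Msmo1 (-0.66 ± 0.13), Nsdhl (-0.54 ± 0.12) and Dhcr7 (-0.66 ± 0.16). Macrophage and monocyte genes rose in 10 of 25 (median 0.88, 15 adjusted over the list alone). Among them were Lgals3 (2.01 ± 0.34), Mrc1 (1.99 ± 0.37) and Gpnmb (1.85 ± 0.35). Antigen presentation genes rose in 8 of 20 (median 0.67, 12 adjusted over the list alone). Among them were the class II genes RT1-Da (1.36 ± 0.28) and RT1-Db1 (1.49 ± 0.37) and their activator Ciita (1.79 ± 0.40). Rises were called in 10 of 25 p53 targets (median 0.38, 13 adjusted over the list alone, camera adjusted p = 4.0e-11). Among them were Cdkn1a (2.28 ± 0.22), Aen (1.15 ± 0.14) and Gdf15 (2.02 ± 0.35). T and NK cell genes rose in 1 of 24 (median 0.24, 3 adjusted over the list alone); the plasminogen activator Plau (1.92 ± 0.26) rose among senescence genes. Neuron markers averaged 9.78 ± 0.78 against 10.27 ± 0.87 (exact permutation adjusted p = 0.68), and no mitosis gene was called, with a median of -0.02. Limma called 334 genes (265 higher, 69 lower), 222 after a shift to a common median and 552 with the neuron markers as a covariate. The count was 107 and 154 without untreated rats 16 and 17 in turn. Leaving out 1 array ended the call of 7 of the 23 genes named here, and Dhcr7 reached adjusted p = 0.1 without untreated rat 16.

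At 8 d (n = 7 and 4) immune transcripts were high and proliferation and matrix transcripts low after MRT. T and NK cell genes rose in 23 of 24 cases (median 2.06, 23 adjusted over the list alone, camera adjusted p = 3.6e-12, adjusted p = 0.29 with an estimated correlation). Among them were Klrk1 (2.05 ± 0.28), Cd8a (3.16 ± 0.44) and Lck (2.60 ± 0.39), and their mean was 8.85 ± 0.63 against 6.82 ± 0.81 (exact permutation adjusted p = 0.0068). Rises were called in 24 of 25 macrophage and monocyte genes (median 1.69, 24 adjusted over the list alone). Among them were Ms4a7 (3.62 ± 0.47), Ccr2 (2.58 ± 0.36) and Fcgr1a (2.41 ± 0.36). Rises were called in 27 of 31 interferon-response genes (median 1.33, 28 adjusted over the list alone). Among them were Irf9 (1.36 ± 0.17), Rsad2 (3.41 ± 0.44) and Herc6 (2.55 ± 0.35). All 20 antigen presentation genes rose (median 1.38, 20 adjusted over the list alone). Among them were RT1-S3 (2.47 ± 0.31), Ciita (2.90 ± 0.41) and Nlrc5 (2.25 ± 0.34). All 27 mitosis genes fell (median -1.63, 27 adjusted over the list alone). Among them were Top2a (-2.13 ± 0.45), Ccnf (-1.16 ± 0.25) and Cdk1 (-1.72 ± 0.39). Replication genes fell in 24 of 26 (median -1.22, 24 adjusted over the list alone). Among them were Pola2 (-1.74 ± 0.31) and E2f1 (-1.38 ± 0.27). MRT rats 37 and 38 had mitosis genes at 7.49 and 7.48 and neuron markers at 10.8; in the other MRT tumours mitosis genes lay at 8.81 to 9.48, and untreated at 10.12 or more. Matrix genes fell in 21 of 24 cases (median -2.42, 22 adjusted over the list alone). Among them were Col3a1 (-3.77 ± 0.41), Col6a1 (-3.80 ± 0.43) and Col6a2 (-4.27 ± 0.50). Hypoxia genes fell in 14 of 22 (median -0.54, 14 adjusted over the list alone). Among them were Car9 (-4.27 ± 0.37), Ndrg1 (-1.63 ± 0.20) and Egln3 (-2.18 ± 0.27). Hypoxia means, 8.92 to 9.44, lay near untreated 6 h ones (8.72 to 9.09). The largest rises included the striatal neuron genes Tac1 (4.45 ± 1.03), Drd1 (4.20 ± 0.96) and Scn4b (3.89 ± 0.68), the actin-severing Scin (4.08 ± 0.55), the T-cell chemokines Ccl17 (3.73 ± 0.43) and Cxcl11 (3.67 ± 0.62) and the interferon-induced Ddx60 (3.68 ± 0.54). The largest falls were the water channel Aqp1 (-5.52 ± 0.67), the methyltransferase Inmt (-5.28 ± 0.63), the collagens Col8a2 (-4.98 ± 0.76) and Col18a1 (-4.69 ± 0.54), the matrix protein Ibsp (-4.68 ± 0.55) and the mesenchymal regulator Prrx2 (-4.41 ± 0.56). Neuron markers averaged 9.93 ± 0.66 against 8.09 ± 0.56 and rose in 18 of 23 (median 1.57, 18 adjusted over the list alone). Among them was Gad1 (2.78 ± 0.55). The myelin genes Mog (2.39 ± 0.53) and Mag (2.24 ± 0.51) and the B-cell marker Ms4a1 (2.32 ± 0.41) rose. Limma called 6797 genes (3093 higher, 3704 lower), 2980 of them past 1 log2, and 4078 (1879 higher and 2199 lower) with the neuron markers as a covariate, 3090 of them shared.

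**Figure D1:**
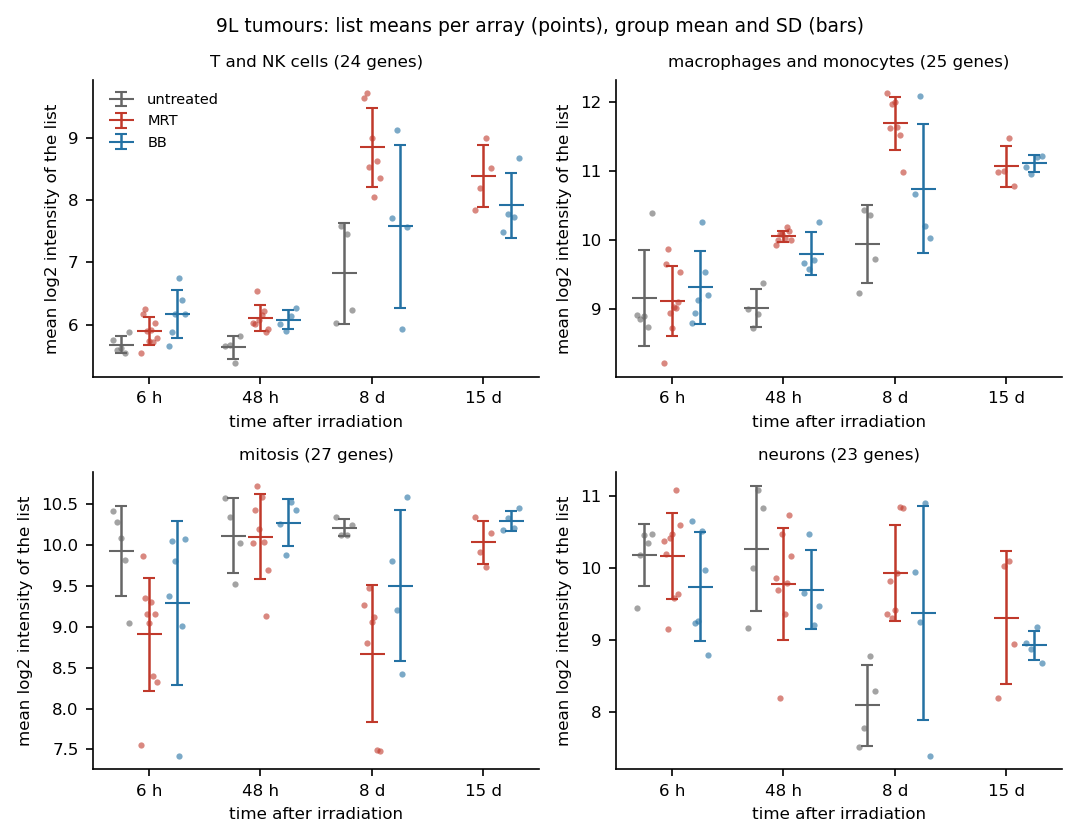
Mean log2 intensity of 4 gene lists in each tumour by treatment and time. T and NK cell genes averaged 6.82 ± 0.81 untreated, 8.85 ± 0.63 after MRT and 7.58 ± 1.31 after BB at 8 d.

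Broad-beam tumours at 6 h (n = 6 and 5) raised transcripts of single chemokines and of p53 targets. Rises were largest for the monocyte chemokines Ccl7 (2.79 ± 0.47) and Ccl2 (2.58 ± 0.40), Cdkn1a (2.03 ± 0.22) and Mgmt (1.94 ± 0.35), the collagenase Mmp13 (1.78 ± 0.64), Tfpi2 (1.73 ± 0.38) and Ptges (1.72 ± 0.28). Falls were largest for Nos1ap (-1.93 ± 0.48), Pacsin1 (-1.89 ± 0.51), Grin2a (-1.83 ± 0.61), Septin5 (-1.70 ± 0.46) and Camk2g (-1.65 ± 0.33), and the other probe sets of Pacsin1 and Camk2g changed by 0.29 and 0.14. Interferon-response genes rose in 14 of 31 cases (median 0.84, 17 adjusted over the list alone). Among them were Rsad2 (2.32 ± 0.42), Cxcl11 (2.99 ± 0.60) and Cxcl10 (2.41 ± 0.49). Targets of p53 rose in 12 of 25 (median 0.50, 12 adjusted over the list alone, camera adjusted p = 3.3e-07). Among them were Aen (1.26 ± 0.14) and Mdm2 (1.07 ± 0.13). Mitosis genes fell in 6 of 27 (median -0.54, 6 adjusted over the list alone). Among them were Plk1 (-1.41 ± 0.34) and Cdc20 (-1.67 ± 0.43). Mitosis genes lay at 7.42 in BB rat 47, 9.01 or more in other BB tumours and 9.04 to 10.42 untreated. Microglia markers fell in 4 of 8 (median -0.66, 4 adjusted over the list alone). Among them were P2ry12 (-1.56 ± 0.43) and Sall1 (-0.67 ± 0.23). Neuron markers averaged 9.74 ± 0.76 against 10.18 ± 0.43 with a median change of -0.51, and of these only the synaptic vesicle gene Syn1 (-1.43 ± 0.51) fell. Limma called 2478 genes (1470 higher, 1008 lower), 24 with only these groups in the fit, and 2556 higher and 737 lower after a shift to a common median. With 1 array left out, 4 of these 22 genes lost the call, and Syn1 reached adjusted p = 0.14 without untreated rat 5.

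In broad-beam tumours at 48 h (n = 4 and 4) p53 targets rose in 5 of 25 cases (median 0.34, 8 adjusted over the list alone, camera adjusted p = 7.7e-06). Among them were Cdkn1a (2.14 ± 0.25), Aen (0.96 ± 0.16) and Pvt1 (1.23 ± 0.24). The largest rises further held the protease Mmp10 (2.96 ± 0.64), the repair enzyme Mgmt (2.71 ± 0.41), the growth factor Areg (2.54 ± 0.61) and Cd8a (2.16 ± 0.50). The largest falls were the vesicular glutamate transporter Slc17a7 (-2.59 ± 0.76), the kinase subunit Pik3r1 (-1.58 ± 0.35) and the transporter Slc6a7 (-1.08 ± 0.24). Macrophage and monocyte genes rose in 6 of 25 (median 0.88, 10 adjusted over the list alone). Among them were Lgals3 (1.79 ± 0.39), Cd14 (1.82 ± 0.41) and Gpnmb (1.59 ± 0.40). The sterol gene Cyp51 (-0.79 ± 0.16) fell. Neuron markers averaged 9.70 ± 0.55 against 10.27 ± 0.87 (exact permutation adjusted p = 0.46), and rat 53 had a Gapdh 3 prime to 5 prime difference of 2.35 log2. Limma called 369 genes (195 higher, 174 lower), 168 after quantile normalization, 87 higher and 308 lower after a shift to a common median, 123 without the dimmest 30 percent of genes and 128 with the Gapdh difference as a covariate. The count was 75, 135 and 176 without untreated rats 16, 17 and 18 in turn and 171, 119, 173 and 193 without BB rats 50, 51, 52 and 53 in turn. Leaving out 1 array ended the call of 7 of the 14 genes named here, and Slc17a7 reached adjusted p = 0.16 without BB rat 52.

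At 8 d after BB (n = 4 and 4) the largest rises were striatal neuron genes, Drd1 (4.33 ± 1.09), Tac1 (3.90 ± 1.17), Scn4b (3.77 ± 0.77) and Drd2 (3.39 ± 1.05), and the regulator Dach1 (3.20 ± 0.92). Falls were largest for the matrix genes Mfap4 (-3.71 ± 0.45) and Omd (-3.45 ± 0.43) and the water channel Aqp1 (-3.64 ± 0.76). Matrix genes fell in 15 of 24 cases (median -1.36, 16 adjusted over the list alone). Among them were Sparc (-1.21 ± 0.23) and Col6a2 (-2.89 ± 0.56). Hypoxia genes fell in 14 of 22 (median -0.71, 15 adjusted over the list alone). Among them were Car9 (-3.13 ± 0.42) and Egln3 (-1.95 ± 0.30). Interferon-response genes rose in 16 of 31 (median 0.88, 18 adjusted over the list alone). Among them were Rsad2 (2.93 ± 0.50), Irf9 (1.05 ± 0.19) and Herc6 (2.05 ± 0.40). Antigen presentation genes rose in 7 of 20 (median 0.81, 15 adjusted over the list alone). Among them was Ciita (2.19 ± 0.46). Only 2 of 24 T and NK cell genes rose, Klrk1 (1.03 ± 0.31) and Lck (1.25 ± 0.44), with a mean of 7.58 ± 1.31 against 6.82 ± 0.81 (exact permutation adjusted p = 0.48). No mitosis gene was called, with a median of -0.72 and of 0.12 with the neuron markers as a covariate. Neuron markers averaged 9.38 ± 1.49 against 8.09 ± 0.56 and rose in 6 of 23 (median 0.91, 7 adjusted over the list alone). Limma called 3255 genes (1189 higher, 2066 lower), 1404 with only these groups in the fit, 1914 with the neuron markers as a covariate, and 1560 higher and 1590 lower after a shift to a common median. The count was 1774 without untreated rat 27 and 2134, 1576 and 4912 without BB rats 54, 55 and 57 in turn. Among the 18 genes named, 5 lost the call when some array was left out, and Lck reached adjusted p = 0.27 without BB rat 55.

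Against the same untreated tumours, MRT and BB moved 119 (85 higher, 34 lower), 141 (105 higher, 36 lower) and 2952 (1042 higher, 1910 lower) genes in the same direction at 6 h, 48 h and 8 d, and no gene in opposite directions. Independent calls would give 19, 4.48 and 797, and data with no effect and shared controls gave a median of 0 and at most 4. The changes correlated at 0.572, 0.802 and 0.927, where shared controls alone gave a median of 0.637, 0.608 and 0.62 and at most 0.929, 0.942 and 0.963. Their covariance was 0.0643, 0.095 and 0.549 against 0.0318, 0.0398 and 0.0428 on average and at most 0.158, 0.212 and 0.211 simulated, so only at 8 d did it exceed every simulation, there by 0.507 over the average. With the untreated tumours divided between the treatments the correlation averaged 0.293, 0.487 and 0.868, with a lowest value of 0.0522, -0.00331 and 0.803, and 14 to 30, 2 to 8 and 512 to 1816 genes moved together.

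**Figure D2:**
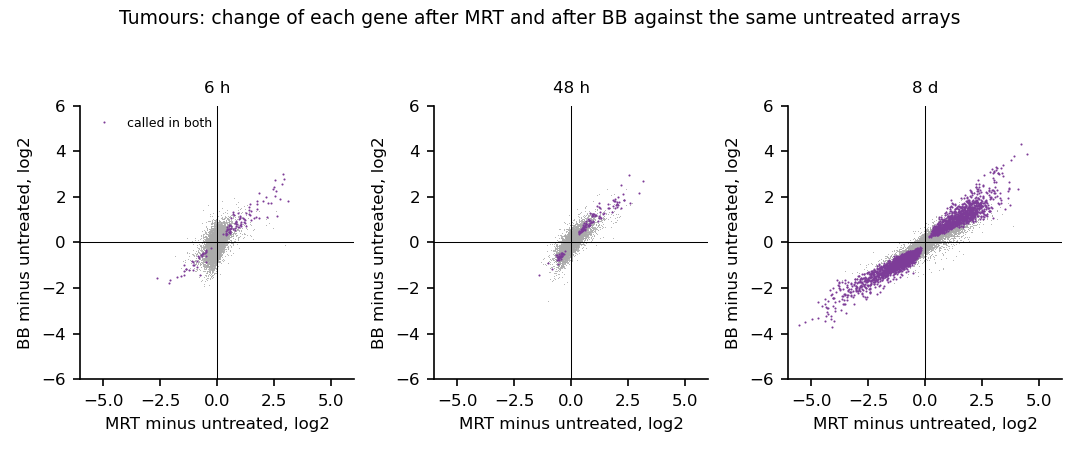
Change of every gene after MRT and after BB in tumours at 6 h, 48 h and 8 d, against shared untreated arrays. The correlations were 0.572, 0.802 and 0.927.

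Compared directly at 6 h (n = 9 and 6), the nuclear factor kappa B inhibitor Tnfaip3 (1.18 ± 0.22) was among the genes highest after MRT relative to BB. Lowest were C2h4orf33 (-1.48 ± 0.19), Bbip1 (-1.07 ± 0.15) and Spa17 (-1.07 ± 0.22). The chemokines Ccl3 (1.82 ± 0.33) and Cxcl2 (3.08 ± 0.58) stood higher, as did the immediate early gene Egr1 (0.82 ± 0.21) and the neutrophil genes S100a8 (1.40 ± 0.42) and Csf3r (0.89 ± 0.29), while the replication genes Rfc4 (-1.04 ± 0.21) and Pcna (-0.48 ± 0.14) were lower. Limma called 2232 genes (787 higher, 1445 lower), 100 past 1 log2 and 612 higher and 1932 lower after a shift to a common median, but 0 with only these groups in the fit (3235 at unadjusted p under 0.05).

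At 48 h limma called 0 genes between MRT and BB tumours (n = 8 and 4, 515 at unadjusted p under 0.05), and neuron markers averaged 9.78 ± 0.78 against 9.70 ± 0.55. At 8 d (n = 7 and 4) MRT tumours had more of the stress cytokine Gdf15 (1.60 ± 0.36), the cornified-envelope gene Sprr1a (1.42 ± 0.36), the glycolysis regulator Pfkfb3 (0.97 ± 0.20), Gpam (0.85 ± 0.19) and Uqcrfs1 (0.30 ± 0.08), and less of the laminin Lama1 (-0.80 ± 0.18) and the fatty acid synthase Fasn (-0.67 ± 0.16). T and NK cell genes were higher in 8 of 24 cases (median 1.32, 21 adjusted over the list alone, camera adjusted p = 2.4e-18, adjusted p = 0.27 with an estimated correlation). Among them were Cd8a (2.14 ± 0.44), Cd2 (1.46 ± 0.33) and Cd8b (1.58 ± 0.36), and their mean was 8.85 ± 0.63 against 7.58 ± 1.31 (exact permutation adjusted p = 0.32). Macrophage and monocyte genes were higher in 2 of 25 (median 0.88, 19 adjusted over the list alone), Cd163 (3.15 ± 0.70) and Cd14 (1.44 ± 0.37), and the collagens Col3a1 (-1.84 ± 0.41) and Col6a1 (-1.82 ± 0.43) were lower. No mitosis gene was called, with a median of -0.84, and neuron markers averaged 9.93 ± 0.66 against 9.38 ± 1.49. Limma called 180 genes (140 higher, 40 lower), 296 (166 higher and 130 lower) after quantile normalization, 111 higher and 106 lower after a shift to a common median, 395 with the neuron markers as a covariate and 0 (1582 at unadjusted p under 0.05) with only these groups in the fit. The count was 0 (2221 at unadjusted p under 0.05), 1459, 13 and 0 (1115 at unadjusted p under 0.05) without BB rats 54, 55, 56 and 57 in turn. Leaving out 1 array ended the call of 14 of the 14 genes named here, and Uqcrfs1 reached adjusted p = 0.39 without BB rat 57.

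At 15 d (n = 4 and 4) MRT tumours had more of the phospholipase Pla2g2d (2.40 ± 0.53), the mast-cell protease Mcpt1 (1.92 ± 0.43), Vch (1.63 ± 0.44) and Ubl5 (1.59 ± 0.35) than BB tumours. The largest differences in the other direction were Zbtb41 (-1.92 ± 0.33), the protease Ctsk (-1.91 ± 0.56) and Drg1 (-1.90 ± 0.28). The plasma-cell genes Mzb1 (1.91 ± 0.48) and Jchain (2.01 ± 0.51) were higher, the hypoxia genes Hk2 (-1.20 ± 0.31) and Kdm3a (-0.52 ± 0.16) lower, and no T or NK cell gene was called, with a median of 0.50. Neuron markers averaged 9.31 ± 0.92 against 8.93 ± 0.20 (exact permutation adjusted p = 0.6). Limma called 433 genes (234 higher, 199 lower), 878 with only these groups in the fit, 746 with the neuron markers as a covariate, 265 with the Gapdh difference as a covariate and 149 higher and 359 lower after a shift to a common median. The count was 214 and 201 without MRT rats 41 and 43 in turn and 145, 179 and 195 without BB rats 58, 59 and 60 in turn. Among the 11 genes named, 6 lost the call when some array was left out, and Ctsk reached adjusted p = 0.22 without BB rat 58.

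The difference between MRT and BB tumours itself changed from 6 h to 8 d for T and NK cell genes, of which 11 of 24 gained (median 1.52, 23 adjusted over the list alone, camera adjusted p = 1.8e-14, adjusted p = 0.63 with an estimated correlation). Among them were Cd8a (2.23 ± 0.58), Cd8b (1.79 ± 0.47) and Cd2 (1.62 ± 0.44). The macrophage genes Ms4a7 (2.31 ± 0.61), Cd163 (3.24 ± 0.92) and Mrc1 (1.72 ± 0.50) gained as well, and the collagens Col6a1 (-2.17 ± 0.56) and Col1a1 (-2.39 ± 0.65) and the sterol regulator Srebf2 (-0.91 ± 0.21) lost. Limma called 675 genes (537 higher, 138 lower), 398 higher and 250 lower after quantile normalization, 1301 with the neuron markers as a covariate and 0 (1754 at unadjusted p under 0.05) with only these groups in the fit. The count was 291, 1466, 208 and 280 without BB 8 d rats 54, 55, 56 and 57 in turn. With 1 array left out, 8 of these 9 genes lost the call, and Mrc1 reached adjusted p = 0.15 without BB 8 d rat 57.

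From 8 d to 15 d after MRT (n = 7 and 4), 23 of 27 mitosis genes rose (median 1.39, 27 adjusted over the list alone). Among them were Ccnf (1.22 ± 0.25), Cdc20 (1.78 ± 0.44) and Prc1 (1.59 ± 0.41). The replication gene Tk1 (1.68 ± 0.40) rose. The largest rises were Car9 (4.16 ± 0.37), Pimreg (3.48 ± 0.57) and Col6a2 (3.46 ± 0.50) and the mesenchymal regulator Twist1 (3.15 ± 0.61). The largest falls were Ugt8 (-2.81 ± 0.61), the prostaglandin synthase Ptgs2 (-2.19 ± 0.52) and Cd300a (-2.03 ± 0.32). The interferon genes Ifih1 (-0.88 ± 0.24) and Ifit3 (-2.15 ± 0.62), the myeloid genes Ccr2 (-1.90 ± 0.36) and Itgam (-1.38 ± 0.32) and the p53 targets Aen (-0.64 ± 0.14) and Fas (-1.06 ± 0.23) fell. Neuron markers averaged 9.31 ± 0.92 against 9.93 ± 0.66, and MRT rats 37 and 38 stood apart at 8 d. With the neuron markers as a covariate the mitosis median was 0.99. Limma called 3966 genes (2285 higher, 1681 lower). The count was 2155 and 2502 without MRT 15 d rats 40 and 43 in turn.

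After BB (n = 4 and 4) hypoxia genes rose in 15 of 22 cases from 8 d to 15 d (median 0.97, 19 adjusted over the list alone, camera adjusted p = 1.0e-28). Among them were Car9 (3.06 ± 0.42), Egln3 (2.21 ± 0.30) and Ndrg1 (1.74 ± 0.22) and the vasodilator Adm (3.48 ± 0.41). F13a1 (3.82 ± 0.52) and Ddit4 (2.03 ± 0.30) rose too, as did the vessel-destabilizing factor Angpt2 (0.96 ± 0.25), while Cpne5 (-1.55 ± 0.39) and the Angpt2 receptor Tek (-1.08 ± 0.24) fell. No mitosis gene was called, with a median of 0.79, and neuron markers averaged 8.93 ± 0.20 against 9.38 ± 1.49. Limma called 241 genes (151 higher, 90 lower), 187 higher and 69 lower after a shift to a common median, 9 with only these groups in the fit, 412 with the neuron markers as a covariate and 155 with the Gapdh difference. The count was 106, 147, 82 and 1265 without BB 8 d rats 54, 55, 56 and 57 in turn and 97, 77, 123 and 123 without BB 15 d rats 58, 59, 60 and 61 in turn. Among the 9 genes named, 3 lost the call when some array was left out, and Cpne5 reached adjusted p = 0.18 without BB 8 d rat 56.

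In the hemisphere opposite to the tumour, MRT raised inflammatory transcripts at 6 h (n = 9 and 5). Rises were largest for the chemokines Ccl2 (7.27 ± 0.37), Cxcl10 (6.03 ± 0.35), Cxcl11 (6.01 ± 0.39), Ccl9 (4.70 ± 0.25) and Ccl7 (4.53 ± 0.35), the interferon-induced Gbp2 (5.65 ± 0.32) and the adhesion molecule Sele (5.08 ± 0.18). Falls were largest for the microglial receptor P2ry12 (-3.29 ± 0.34), Prom1 (-2.37 ± 0.16) and the barrier transporters Slco1a4 (-2.36 ± 0.23) and Abcg2 (-2.07 ± 0.19). Cytokine and adhesion genes rose in 18 of 20 (median 2.73, 18 adjusted over the list alone, camera adjusted p = 1.1e-56). Among them was Icam1 (3.65 ± 0.23). Rises were called in 28 of 31 interferon-response genes (median 1.51, 29 adjusted over the list alone, camera adjusted p = 3.8e-55). Targets of p53 rose in 14 of 25 (median 0.78, 16 adjusted over the list alone, camera adjusted p = 2.4e-22). Among them were Cdkn1a (3.92 ± 0.19), Fas (3.13 ± 0.17) and Aen (2.06 ± 0.11). Antigen presentation genes rose in 16 of 20 (median 1.11, 17 adjusted over the list alone, camera adjusted p = 1.3e-20). Among them were Psmb9 (2.62 ± 0.27) and Tap1 (2.09 ± 0.22). Reactive astrocyte genes rose in 11 of 14 (median 1.68, 12 adjusted over the list alone, camera adjusted p = 2.2e-27). Among them were S1pr3 (2.45 ± 0.19) and Timp1 (4.16 ± 0.37), and the neutrophil genes S100a9 (4.03 ± 0.40) and S100a8 (2.82 ± 0.32) rose. Endothelial genes fell in 12 of 20 (median -0.99, 13 adjusted over the list alone, camera adjusted p = 1.3e-13). Microglia markers fell in 6 of 8 (median -0.85, 7 adjusted over the list alone, camera adjusted p = 6.4e-12). Among them were Sall1 (-0.94 ± 0.13) and Gpr34 (-1.82 ± 0.27), while Angpt2 (2.94 ± 0.24) rose and neuron markers averaged 11.12 ± 0.29 against 11.10 ± 0.24. Limma called 1169 genes (762 higher, 407 lower), 307 past 1 log2.

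At 48 h (n = 7 and 4) the largest contralateral rises were the class II genes RT1-Da (4.26 ± 0.37) and RT1-Bb (4.19 ± 0.37), although another probe set of RT1-Bb was called at -0.42, the protease inhibitor Slpi (3.97 ± 0.56), the oxidase subunit Cybb (3.95 ± 0.29), Ccl2 (3.77 ± 0.41) and the class II Cd74 (3.66 ± 0.30) and RT1-Db1 (3.62 ± 0.37). The largest falls were Tnnc2 (-2.02 ± 0.23), the oligodendrocyte-precursor receptor Pdgfra (-1.51 ± 0.21) and Bmp4 (-1.48 ± 0.19). Antigen presentation genes rose in 17 of 20 (median 1.05, 17 adjusted over the list alone, camera adjusted p = 9.1e-20). Macrophage genes rose in 18 of 25 (median 1.26, 20 adjusted over the list alone, camera adjusted p = 4.8e-20). Among them were Gpnmb (3.25 ± 0.25) and Lgals3 (3.30 ± 0.29). Rises were called in 14 of 25 p53 targets (median 0.71, 14 adjusted over the list alone, camera adjusted p = 1.7e-11). Among them were Phlda3 (2.24 ± 0.17) and Mdm2 (1.17 ± 0.11). Reactive astrocyte genes rose in 11 of 14 (median 1.09, 12 adjusted over the list alone, camera adjusted p = 2.0e-12). Among them were Gfap (2.61 ± 0.25), Vim (2.74 ± 0.28) and Timp1 (3.09 ± 0.41), and the precursor gene Enpp6 (-0.94 ± 0.19) fell. Limma called 4579 genes (1873 higher, 2706 lower) with a median of all genes of -0.11, 336 past 1 log2, 430 with only these groups in the fit, 2698 without the dimmest 30 percent and 1521 higher and 4407 lower after a shift to a common median. The untreated array of rat 18 stands apart, as given below, and without it the count was 1214 (816 higher, 398 lower).

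By 8 d (n = 6 and 4) the protease Mmp12 (4.00 ± 0.23), the interferon-induced Mx1 (3.51 ± 0.39) and Rsad2 (3.25 ± 0.37), Cybb (3.49 ± 0.29), the phagocyte lectin Clec7a (3.45 ± 0.34) and Mgmt (3.17 ± 0.15) were the largest rises. Falls were largest for Sult1a1 (-2.67 ± 0.22), Tnnc2 (-1.95 ± 0.24) and Gpd1 (-1.91 ± 0.28), the precursor genes Vcan (-2.16 ± 0.41) and Pdgfra (-2.11 ± 0.22) and the microglial Tmem119 (-1.81 ± 0.33). Untreated rat 30 stood apart, with mitosis genes at 7.32 (others at most 6.54) and matrix genes at 9.61 (at most 8.24); without it Vcan changed by -1.65 and Pdgfra by -1.93, both called. Interferon-response genes rose in 26 of 31 (median 1.43, 29 adjusted over the list alone, camera adjusted p = 9.3e-38). Among them were Irf7 (2.76 ± 0.24) and Usp18 (2.59 ± 0.28). Macrophage genes rose in 14 of 25 (median 0.92, 16 adjusted over the list alone, camera adjusted p = 7.9e-16). Among them was Cd68 (2.34 ± 0.23). Targets of p53 rose in 12 of 25 (median 0.47, 14 adjusted over the list alone, camera adjusted p = 2.3e-14). Among them were Phlda3 (2.06 ± 0.17), Fas (2.29 ± 0.20) and Cdkn1a (2.50 ± 0.22). Glucocorticoid targets fell in 8 of 15 (median -0.46, 8 adjusted over the list alone, camera adjusted p = 1.1e-10). Among them were Fkbp5 (-1.24 ± 0.16) and Sgk1 (-1.33 ± 0.22). Limma called 1124 genes (812 higher, 312 lower), 678 higher and 514 lower after quantile normalization, 592 higher and 624 lower after a shift to a common median, 1743 with only these groups in the fit and 1852 without the untreated 48 h array of rat 18. The count was 735 without untreated rat 28.

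The broad beam raised Ccl2 (6.13 ± 0.40), Gbp2 (5.43 ± 0.34), Cxcl10 (5.38 ± 0.38), Cxcl11 (5.34 ± 0.42), Sele (4.38 ± 0.20), Ccl9 (4.19 ± 0.28), Gbp7 (3.91 ± 0.33) and Angpt2 (3.49 ± 0.26) in the opposite hemisphere at 6 h (n = 6 and 5). The largest falls were P2ry12 (-2.59 ± 0.37), Prom1 (-2.15 ± 0.18), Abcg2 (-1.99 ± 0.20) and Slco1a4 (-1.90 ± 0.25) and the channel subunit Cacng3 (-1.88 ± 0.35). Interferon-response genes rose in 26 of 31 (median 1.56, 28 adjusted over the list alone, camera adjusted p = 7.4e-30). Cytokine and adhesion genes rose in 12 of 20 (median 1.19, 13 adjusted over the list alone, camera adjusted p = 1.3e-14). Targets of p53 rose in 14 of 25 (median 0.45, 15 adjusted over the list alone, camera adjusted p = 1.6e-14), while endothelial genes fell in 13 of 20 (median -0.58, 14 adjusted over the list alone). Limma called 3064 genes (1268 higher, 1796 lower), 2025 with the Gapdh difference as a covariate. The count was 1881 without untreated rat 3.

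At 48 h after BB (n = 3 and 4) the opposite hemisphere showed rises of Cdkn1a (3.13 ± 0.26) and Mgmt (2.59 ± 0.18), the fucosyltransferase Fut9 (2.37 ± 0.50), RT1-Da (2.17 ± 0.46), C1s (2.17 ± 0.31) and Ephx1 (1.99 ± 0.24) and the astrocyte genes Gfap (1.93 ± 0.30) and Vim (1.69 ± 0.34), and falls of Htr5b (-1.78 ± 0.41), Cox5a (-1.60 ± 0.45) and Pdgfra (-1.53 ± 0.26). Rises were called in 11 of 25 p53 targets (median 0.53, 12 adjusted over the list alone, camera adjusted p = 4.2e-08). Among them were Phlda3 (1.72 ± 0.20) and Fas (1.52 ± 0.23), and Cd74 (1.74 ± 0.37) and Cybb (1.93 ± 0.35) rose. Limma called 3069 genes (918 higher, 2151 lower) with a median of all genes of -0.15, 3 with only these groups in the fit and 1514 without the dimmest 30 percent. The count was 5151, 5065 and 501 without untreated rats 16, 17 and 18 in turn and 1414, 836 and 1167 without BB rats 50, 51 and 52 in turn. Without rat 18 the calls were 251 higher and 250 lower. Leaving out 1 array ended the call of 1 of the 15 genes named here, and Cox5a reached adjusted p = 0.079 without untreated rat 18.

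At 8 d after BB (n = 4 and 4) the Wnt modulator Sostdc1 (4.07 ± 0.97), F5 (3.38 ± 0.84), the choroid plexus genes Otx2 (2.72 ± 0.69), whose other probe set changed by -0.02, and Ttr (5.01 ± 1.22) and the striatal genes Dach1 (3.11 ± 0.74), Drd1 (2.65 ± 0.65), Adora2a (2.62 ± 0.80) and Slc35d3 (2.46 ± 0.68) had risen, and Sult1a1 (-2.28 ± 0.24), Ptk2b (-1.69 ± 0.36), Gpd1 (-1.36 ± 0.31) and Pdgfra (-1.35 ± 0.24) had fallen. Interferon-response genes rose in 13 of 31 (median 0.63, 16 adjusted over the list alone). Among them were Usp18 (1.98 ± 0.30) and Irf7 (1.52 ± 0.26). The list means of rats 54 to 57 were 7.04, 8.25, 6.97 and 8.38, and untreated at most 7.00. Targets of p53 rose in 6 of 25 (median 0.14, 6 adjusted over the list alone). Among them were Cdkn1a (1.62 ± 0.24) and Aen (0.95 ± 0.14), and Sgk1 (-0.85 ± 0.24) fell. Limma called 844 genes (460 higher, 384 lower), 382 higher and 640 lower after a shift to a common median, 203 with the Gapdh difference, 1721 without the untreated 48 h array of rat 18 and 79 without the arrays of rats 30, 57, 59 and 60. The count was 227 and 345 without untreated rats 28 and 30 in turn and 382, 511 and 358 without BB rats 54, 55 and 57 in turn. Among the 17 genes named, 8 lost the call when some array was left out, and Adora2a reached adjusted p = 0.13 without untreated rat 30.

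**Figure D3:**
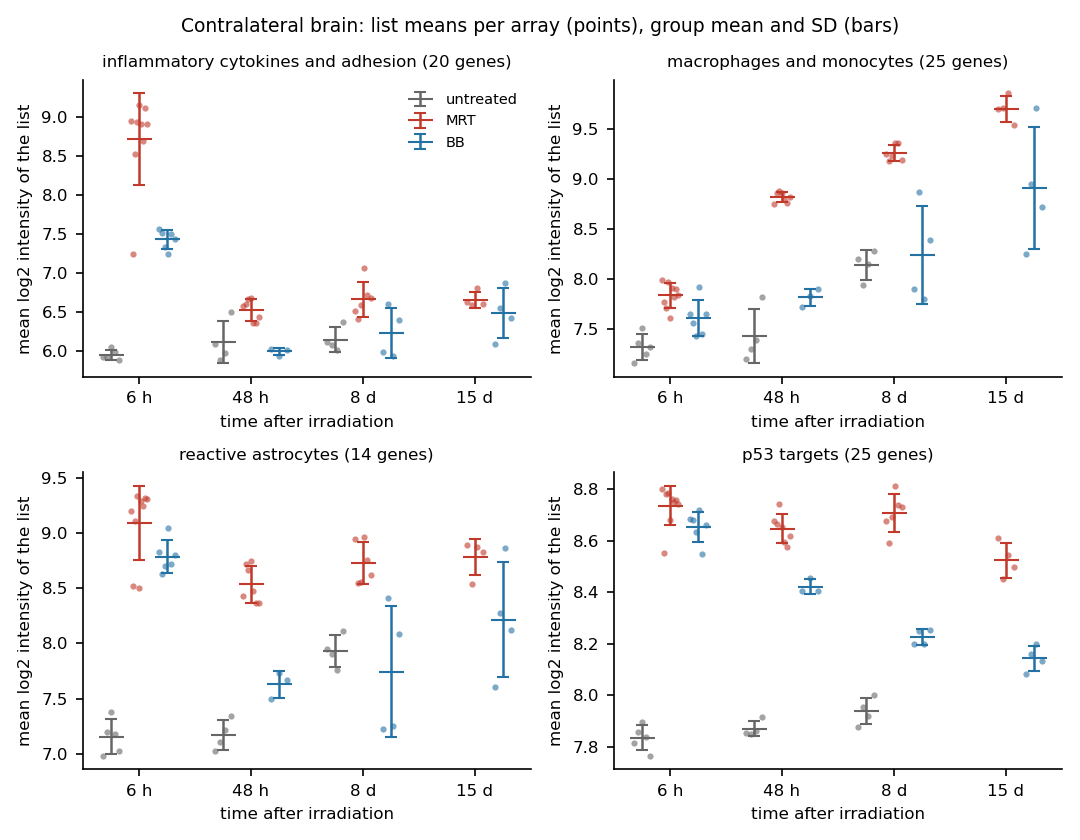
Mean log2 intensity of 4 gene lists in each contralateral sample. Macrophage and monocyte genes averaged 8.14 ± 0.15 untreated, 9.26 ± 0.08 after MRT and 8.24 ± 0.49 after BB at 8 d.

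Between the beams, contralateral samples at 6 h (n = 9 and 6) had more granulocyte and inflammatory transcripts after MRT, Csf3r (1.33 ± 0.20), Socs3 (1.18 ± 0.16) and Rgs16 (1.09 ± 0.20). Siglec5 (1.27 ± 0.14), a member of the microglia list, was higher too, and Mybl1 (-0.64 ± 0.17) and Plxna2 (-0.52 ± 0.12) were lower. Cytokine and adhesion genes were higher in 17 of 20 (median 1.18, 17 adjusted over the list alone, camera adjusted p = 7.3e-28). Among them were Il6 (1.81 ± 0.19), Il1b (2.54 ± 0.28) and Cxcl2 (2.86 ± 0.32). Neutrophil genes were higher in 6 of 10 (median 0.78, 6 adjusted over the list alone, camera adjusted p = 9.1e-10). Among them were Il1r2 (1.63 ± 0.22) and S100a8 (1.90 ± 0.30). Limma called 767 genes (542 higher, 225 lower), 54 with only these groups in the fit, 1966 without the untreated 48 h array of rat 18, 124 with the Gapdh difference as a covariate and 435 higher and 408 lower after a shift to a common median.

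At 48 h (n = 7 and 3) the chemokine Ccl2 (2.67 ± 0.46), the receptors Lilrb4 (2.40 ± 0.44) and Clec7a (2.29 ± 0.36) and Slpi (2.22 ± 0.61), RT1-Ba (2.15 ± 0.42), RT1-Db1 (2.14 ± 0.41) and Timp1 (2.11 ± 0.46) were higher after MRT and the receptor genes Htr2a (-1.51 ± 0.35) and Gabra3 (-1.11 ± 0.30) with Tnnc2 (-0.96 ± 0.25) and Sema3a (-0.86 ± 0.21) lower. Macrophage and monocyte genes were higher in 14 of 25 (median 1.02, 21 adjusted over the list alone, camera adjusted p = 5.0e-26). Among them were Gpnmb (1.78 ± 0.27) and Cybb (2.03 ± 0.31). Antigen presentation genes were higher in 9 of 20 (median 0.77, 17 adjusted over the list alone, camera adjusted p = 1.9e-22). Limma called 276 genes (237 higher, 39 lower), 563 with only these groups in the fit and 212 higher and 70 lower after a shift to a common median. The count was 93, 161 and 131 without BB rats 50, 51 and 52 in turn. Leaving out 1 array ended the call of 6 of the 13 genes named here, and Tnnc2 reached adjusted p = 0.43 without BB rat 50.

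Myeloid genes were also higher after MRT at 8 d (n = 6 and 4), with Mmp12 (3.48 ± 0.23), Gpnmb (2.31 ± 0.26), Lgals3 (2.08 ± 0.30), Clec7a (1.94 ± 0.34) and Cybb (1.89 ± 0.29), the small heat-shock gene Hspb1 (2.43 ± 0.34), the complement inhibitor Serping1 (2.17 ± 0.21) and Atf3 (1.96 ± 0.34) higher, and Tnnc2 (-1.23 ± 0.24) and Agt (-0.94 ± 0.25) lower. Macrophage and monocyte genes were higher in 18 of 25 (median 1.05, 20 adjusted over the list alone, camera adjusted p = 2.3e-28) and averaged 9.26 ± 0.08 against 8.24 ± 0.49. Reactive astrocyte genes were higher in 8 of 14 (median 1.00, 12 adjusted over the list alone, camera adjusted p = 4.4e-15). Among them were Aspg (0.98 ± 0.18) and Gfap (1.24 ± 0.26). Targets of p53 were higher in 10 of 25 (median 0.32, 11 adjusted over the list alone, camera adjusted p = 1.1e-11). Among them were Phlda3 (1.30 ± 0.17) and Gdf15 (1.71 ± 0.23). Limma called 429 genes (369 higher, 60 lower) and 801 without the untreated 48 h array of rat 18. The count was 163 without BB rat 54. Among the 14 genes named, 1 lost the call when some array was left out, and Agt reached adjusted p = 0.2 without BB rat 54.

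At 15 d (n = 4 and 4) Mmp12 (3.86 ± 0.25), Serping1 (2.56 ± 0.24), Igfbp2 (2.22 ± 0.28), Trh (2.16 ± 0.57), Gpnmb (2.04 ± 0.28) and Chi3l1 (2.03 ± 0.20) were higher after MRT and Lox (-2.44 ± 0.44) and Ptgs1 (-1.73 ± 0.33) lower. Cholesterol synthesis genes were lower (median -0.53, 12 adjusted over the list alone, camera adjusted p = 1.3e-14), with Msmo1 (-0.84 ± 0.12) and Sqle (-0.89 ± 0.14), and mitosis genes lower in 10 of 27 (median -0.95, 24 adjusted over the list alone). Among them was Ccnb1 (-0.87 ± 0.21), and the BB arrays of rats 59 and 60 stand high in them. Limma called 834 genes (585 higher, 249 lower), 516 higher and 361 lower after quantile normalization, 507 higher and 442 lower after a shift to a common median, 1929 with only these groups in the fit and 325 without the arrays of rats 30, 57, 59 and 60. The count was 438 and 342 without MRT rats 41 and 42 in turn and 407 and 499 without BB rats 59 and 60 in turn. With 1 array left out, 2 of these 11 genes lost the call, and Trh reached adjusted p = 0.13 without MRT rat 42.

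From 6 h to 8 d the contralateral difference between the beams grew for macrophage genes (median 0.54, 11 adjusted over the list alone, camera adjusted p = 5.1e-16). Among them were Gpnmb (2.51 ± 0.33), Lgals3 (2.01 ± 0.38) and C1qa (1.24 ± 0.25). It also grew for p53 targets (median 0.42, 13 adjusted over the list alone, camera adjusted p = 1.9e-08), among them Gdf15 (1.43 ± 0.29) and Mdm2 (0.71 ± 0.15). It shrank for cytokine and adhesion genes (median -0.67, 12 adjusted over the list alone, camera adjusted p = 1.3e-14). Among them were Il6 (-1.61 ± 0.30), Cxcl2 (-2.66 ± 0.51) and Ccl20 (-2.29 ± 0.44). Limma called 135 genes (110 higher, 25 lower). The count was 60 and 83 without BB 8 d rats 54 and 56 in turn.

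Tested as a difference between the tissues, the MRT effect at 6 h was lower in tumour for interferon-response genes (median -0.66, 14 adjusted over the list alone, camera adjusted p = 2.7e-39). Among them were Gbp2 (-4.65 ± 0.41) and Ifitm3 (-2.26 ± 0.31). It was also lower for cytokine and adhesion genes (median -1.10, 10 adjusted over the list alone, camera adjusted p = 2.9e-24), among them Ccl2 (-4.41 ± 0.53), Sele (-2.47 ± 0.40) and Icam1 (-2.09 ± 0.37). The same held for Psmb9 (-2.69 ± 0.37), RT1-Da (-2.32 ± 0.43) and Timp1 (-4.05 ± 0.44) and for the p53 targets Fas (-1.70 ± 0.27), Phlda3 (-1.48 ± 0.26) and Cdkn1a (-1.39 ± 0.28), while the effect was higher for Abcb1a (1.99 ± 0.33). Limma called 126 genes (17 higher, 109 lower) and 83 with only these groups in the fit. At 48 h the effect was lower in tumour for RT1-Da (-2.90 ± 0.48), Cd74 (-2.59 ± 0.44), Vim (-2.78 ± 0.30) and Gfap (-2.47 ± 0.42) and higher for Cd8a (2.87 ± 0.51). Limma called 352 genes (205 higher, 147 lower) with a median of all genes of 0.11, 70 with only these groups in the fit, 887 with the rat as a replicate block, 682 with the difference per rat and 41 without the arrays of rats 18 and 53. The count was 214 and 94 without tumour untreated rats 15 and 16 in turn and 1233, 1330, 1451 and 45 without contralateral untreated rats 15, 16, 17 and 18 in turn. At 8 d the effect was higher in tumour for 21 of 24 T and NK cell genes (median 1.86, 23 adjusted over the list alone). Among them were Cd8a (2.93 ± 0.52), Lck (2.35 ± 0.42) and Cd5 (3.18 ± 0.58), beside the macrophage receptor Cd163 (4.43 ± 0.77). It was lower for 17 of 24 matrix genes (median -1.88, 18 adjusted over the list alone), among them Mmp2 (-3.66 ± 0.51) and Col1a1 (-3.55 ± 0.61), for 12 of 25 p53 targets, among them Phlda3 (-2.42 ± 0.30) and Mdm2 (-1.20 ± 0.18), and for Car9 (-3.73 ± 0.47). Limma called 5259 genes (2194 higher, 3065 lower), 2673 higher and 2411 lower after a shift to a common median.

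The difference between MRT and BB was itself compared between the tissues, where a change common to all BB arrays of a time would cancel. At 6 h limma called 440 genes (108 higher, 332 lower), with Egr1 (1.08 ± 0.31) and Rfc4 (-0.89 ± 0.25), 842 with the rat as a replicate block, 855 without the arrays of rats 18 and 53, and 0 (2322 at unadjusted p under 0.05) with only these groups in the fit. At 48 h limma called 0 (1098 at unadjusted p under 0.05), 15 with the replicate block, 47 with the difference per rat and 71 with only these groups in the fit. The count was 1 without contralateral BB rat 51 and 1 without tumour BB rat 52. At 8 d it called 4, with Hspb1 (-2.06 ± 0.42) lower, 41 with the replicate block, 87 with the difference per rat and 0 (953 at unadjusted p under 0.05) with only these groups in the fit; scaling gave 17 and 11, and no T or NK cell gene was called over all genes (median 1.14, 18 adjusted over the list alone). The count was 0 (937 at unadjusted p under 0.05), 0 (1018 at unadjusted p under 0.05) and 11 without contralateral BB rats 54, 56 and 57 in turn and 2, 344, 0 (1984 at unadjusted p under 0.05) and 1 without tumour BB rats 54, 55, 56 and 57 in turn. At 15 d it called 8, 38 with the replicate block, 39 with the difference per rat, 220 with only these groups in the fit and 16 with the mean of all probe sets, and macrophage genes had a median of -0.81. In this comparison the count was 1 without tumour MRT rat 40, 3, 5 and 5 without contralateral MRT rats 40, 41 and 42 in turn, 3, 21 and 5 without contralateral BB rats 59, 60 and 61 in turn and 2 and 5 without tumour BB rats 58 and 60 in turn.

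**Figure D4:**
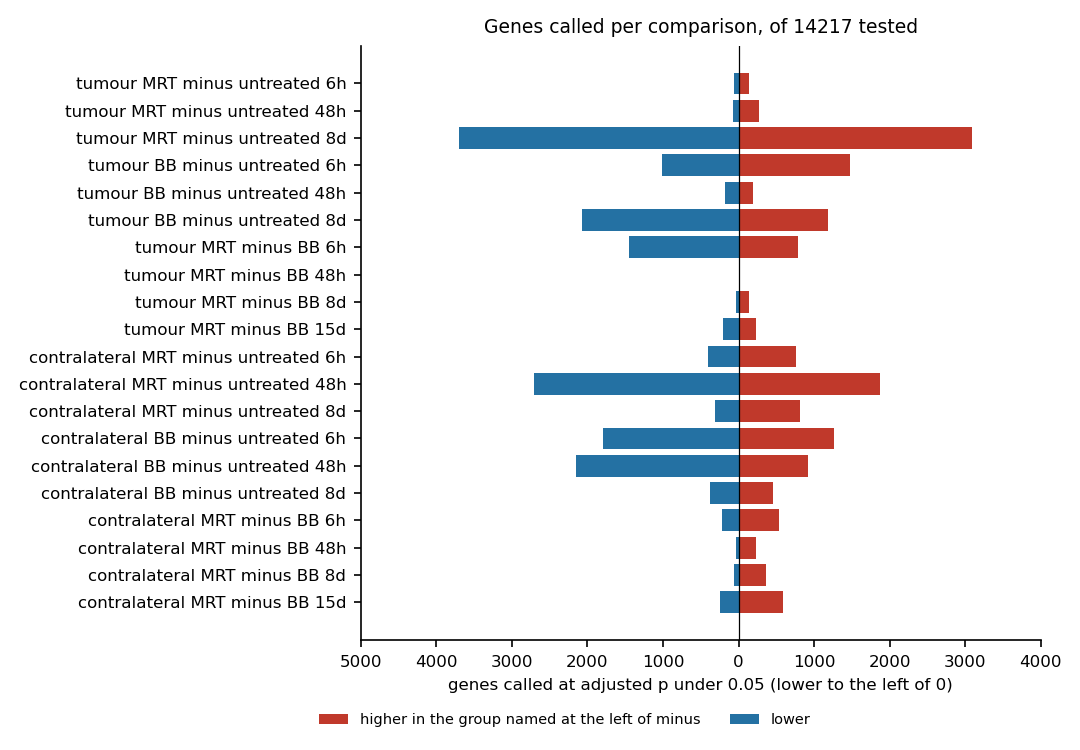
Genes called higher or lower in each comparison of groups within a tissue. The largest count was 6797 in MRT tumours at 8 d and the smallest 0 between MRT and BB tumours at 48 h.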

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

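The comparisons between tissues and times and the tests of an offset in the BB arrays at 6 h were planned; the other tests in this part were chosen only after the results they bear on were seen. In 5 measures of 21 groups, 105 pairs of group and measure, 6 values, from 5 arrays, lay far from the rest of their group, and chance alone gives about 1 in 20 pairs. The contralateral untreated 48 h array of rat 18 had T and NK cell genes at 6.18, against 5.37 for the nearest array, and mitosis genes at 6.76 against 5.78. It departs as a whole, with a median intensity of 165, a correlation of 0.904 with its group and Gapdh at 11.7, where the others had 123 to 125, at least 0.984 and at least 13.2. Its T and NK cell genes lay above those of every untreated 48 h tumour (at most 5.82) and its matrix genes at 7.69, where those tumours had at least 10.63, so neither a tumour under its name nor a share of tumour tissue alone gives these values. The untreated tumour of rat 5 at 6 h had macrophage and monocyte genes at 10.4 against 8.92, and that of rat 1 neuron markers at 9.44 against 10.19. The contralateral MRT array of rat 43 at 15 d had mitosis genes at 6.56 against 6.11. In the BB tumour of rat 53 at 48 h the Gapdh 3 prime to 5 prime difference was 2.35 log2 against 0.394.

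Tests of a difference between tissues or times with called genes, counted above, were marked next. A signal also lay in the 9780 probe sets without a gene symbol, which no comparison used. Of these, 2791 (1222 higher, 1569 lower) were called between MRT and untreated tumours at 8 d, and 278 (157 higher, 121 lower) between MRT and untreated contralateral samples at 6 h.

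T and NK cell genes were higher in MRT than in untreated tumours at 8 d. More brain tissue in the MRT samples was tested, and the lowest MRT tumour lay 2.13 log2 above the highest contralateral MRT array in these genes, so brain tissue cannot supply them. Fewer tumour cells would raise other cell types alike, but the mean of these genes rose by more than 2 standard errors over 3 of 4 other lists, by 1.97 ± 0.48 over endothelium, 2.44 ± 0.48 over pericytes and 2.44 ± 0.35 over microglia, though by only 0.27 ± 0.26 over macrophages. Medians changed by 2.06 for T and NK cells, 1.69 for macrophages and 1.57 for neurons, and by 0.01, -0.43 and -0.12 for those 3 lists. More brain tissue was thus not the whole cause. The test of fewer tumour cells decides nothing, since macrophage and neuron genes rose as well. MRT may also change the other lists by itself, as endothelial and microglia markers fell at 6 h after MRT. A gain of T and NK cells or of their transcripts, wholly or in part from a loss of tumour cells that may have raised macrophage genes as well, is left open.

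Between MRT and BB tumours at 6 h, 2232 genes were called. An offset common to all BB arrays would recur at 48 h, where the signed median was -0.00426 of that at 6 h, and one common to both tissues would recur in contralateral samples at 6 h, where it was 0.188. There 71.0 percent of the called genes had the same sign, so a smaller common part may be present. With the Gapdh difference as a covariate 80.1 percent as many genes were called, which speaks against RNA degradation as the whole cause. The called genes varied 1.63 times as much within these groups as in the pooled spread, against 1.29 for all genes, so a part of the calls may come from a spread that the pooled variance understates. In line with that, the fit of only these groups called 0 genes (3235 at unadjusted p under 0.05), and no biological cause was tested.

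Macrophage and reactive astrocyte genes were higher in contralateral tissue after MRT than after BB at 8 d, by a median of 1.05 for macrophages. An offset common to all BB arrays would be equal at 6 h and 8 d, but the macrophage difference grew by 0.545. Tumour cells would bring matrix genes (median difference 0.0488), but BB rat 57 stood high in them (8.79, others at most 7.90), so this decides nothing. The offset is excluded as the whole cause. Dose or beam cannot be told apart from a label-set difference after 6 h. Medians at 6 h, 48 h and 15 d were 0.11, 1.02 and 0.83.

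Samples of both groups were also divided in other ways, and the divisions with at least as many calls as the real one, itself included, were counted; brackets hold the real count and the highest of the others. Chance cannot be excluded, with a share of 0.05 or more, for tumour BB against untreated 2 of 35 (3255, 3588) at 8 d, tumour MRT against BB 12 of 100 (180, 3769) at 8 d, contralateral BB against untreated 5 of 35 (3069, 5141) at 48 h, the MRT effect between tissues 10 of 100 (352, 1067) at 48 h and MRT against BB between tissues 19 of 100 (4, 2583) at 8 d. With the difference per rat as the measure the divisions gave the MRT effect between tissues 1 of 100 (174, 21) at 6 h, 5 of 100 (682, 1228) at 48 h, 1 of 84 (4679, 2430) at 8 d and MRT against BB between tissues 1 of 100 (657, 641) at 6 h, 3 of 100 (47, 820) at 48 h, 12 of 100 (87, 2031) at 8 d, 1 of 35 (39, 2) at 15 d. Chance is left open for MRT against BB between tissues 5 of 100 (440, 1486) at 6 h, 6 of 100 (8, 70) at 15 d, where the share was under 0.05 per rat but not without the pairing. A count of 0 is reached by every division, so nothing was decided for tumour MRT against BB 100 of 100 (0, 1864) at 48 h and MRT against BB between tissues 100 of 100 (0, 24) at 48 h without the pairing; per rat the share of the latter was under 0.05. Chance was excluded at that share for tumour MRT against untreated 2 of 100 (202, 282) at 6 h, 1 of 100 (334, 120) at 48 h, 1 of 100 (6797, 5291) at 8 d, tumour BB against untreated 1 of 100 (2478, 2424) at 6 h, 1 of 35 (369, 1) at 48 h, tumour MRT against BB 3 of 100 (2232, 2844) at 6 h, 1 of 35 (433, 5) at 15 d, tumour MRT against BB, change to 8 d 4 of 100 (675, 2573), contralateral MRT against untreated 4 of 100 (1169, 2552) at 6 h, 1 of 100 (4579, 3607) at 48 h, 1 of 100 (1124, 184) at 8 d, contralateral BB against untreated 1 of 100 (3064, 1626) at 6 h, 1 of 35 (844, 80) at 8 d, contralateral MRT against BB 1 of 100 (767, 40) at 6 h, 2 of 100 (276, 287) at 48 h, 1 of 100 (429, 119) at 8 d, 1 of 35 (834, 112) at 15 d, contralateral MRT against BB, change to 8 d 1 of 100 (135, 10), the MRT effect between tissues 4 of 100 (126, 923) at 6 h, 2 of 100 (5259, 5351) at 8 d, untreated tumour against contralateral 1 of 100 (11526, 10131), untreated tumour 8 d against 6 h 1 of 100 (4151, 3613), tumour MRT 15 d against 8 d 1 of 100 (3966, 1287) and tumour BB 15 d against 8 d 1 of 35 (241, 23).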

How the results depend on the processing

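The alternatives with the neuron markers, with the Gapdh difference, without the arrays of rats 18 and 53 and without the contralateral arrays of rats 30, 57, 59 and 60 were chosen after seeing the data. Counts are named where they moved by more than 1.5 times, and the cause was not tested except where fewer arrays or genes were fitted. Groups of 3 to 5 arrays and whole-number intensity, with a step of 0.19 log2 at the lowest value, limit what can be called. A correction between label sets was not run, since within a tissue none can be fitted; the comparisons between tissues and between time points stand in for it.

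No count moved without the intensity trend or with the robust prior, and 0 and 1 of 439 named gene results lost their call. Quantile normalization gave tumour BB against untreated 168 at 48 h, tumour MRT against BB 296 at 8 d and MRT against BB between tissues 17 at 8 d, and 5 gene and 2 list results lost their call. A shift to a common median gave tumour MRT against untreated 222 at 48 h and MRT against BB between tissues 11 at 8 d, with 3 gene results lost. Without the dimmest 30 percent of genes the counts were tumour BB against untreated 123 at 48 h, tumour MRT against BB 72 at 8 d, contralateral MRT against untreated 2698 at 48 h, contralateral BB against untreated 1514 at 48 h and MRT against BB between tissues 2 at 8 d, and 1 gene and 8 list results were lost. The mean of all probe sets gave MRT against BB between tissues 16 at 15 d, and 10 gene results were lost.

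Array quality weights, whose estimation gave convergence warnings, gave tumour MRT against untreated 2280 at 6 h, 666 at 48 h, tumour BB against untreated 2392 at 48 h, 9451 at 8 d, tumour MRT against BB 43 at 48 h, 5236 at 8 d, 2628 at 15 d, tumour MRT against BB, change to 8 d 3334, untreated tumour 8 d against 6 h 7300, tumour BB 15 d against 8 d 8910, contralateral MRT against untreated 2473 at 6 h, 1898 at 48 h, 2050 at 8 d, contralateral BB against untreated 4816 at 6 h, 1714 at 48 h, 2644 at 8 d, contralateral MRT against BB 3095 at 6 h, 952 at 48 h, 2697 at 8 d, 4978 at 15 d, contralateral MRT against BB, change to 8 d 760, the MRT effect between tissues 762 at 6 h, 163 at 48 h and MRT against BB between tissues 1546 at 48 h, 0 (556 at unadjusted p under 0.05) at 8 d, 1058 at 15 d. With them 4 gene results were lost.

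With only the groups compared in the fit the counts were tumour MRT against untreated 70 at 6 h, tumour BB against untreated 24 at 6 h, 1404 at 8 d, tumour MRT against BB 0 (3235 at unadjusted p under 0.05) at 6 h, 0 (1582 at unadjusted p under 0.05) at 8 d, 878 at 15 d, tumour MRT against BB, change to 8 d 0 (1754 at unadjusted p under 0.05), contralateral MRT against untreated 430 at 48 h, 1743 at 8 d, contralateral BB against untreated 3 at 48 h, contralateral MRT against BB 54 at 6 h, 563 at 48 h, 1929 at 15 d, the MRT effect between tissues 83 at 6 h, 70 at 48 h, MRT against BB between tissues 0 (2322 at unadjusted p under 0.05) at 6 h, 71 at 48 h, 0 (953 at unadjusted p under 0.05) at 8 d, 220 at 15 d and tumour BB 15 d against 8 d 9. There 96 of 439 gene results and 2 of 109 list results were lost, in fits with fewer arrays to estimate the spread. An estimated correlation between genes ended 62 of the 109 list results, and the 47 others were on the same side of the threshold.

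With the rat as a random replicate block the counts were the MRT effect between tissues 887 at 48 h and MRT against BB between tissues 842 at 6 h, 15 at 48 h, 41 at 8 d, 38 at 15 d, and as a difference per rat the MRT effect between tissues 682 at 48 h and MRT against BB between tissues 47 at 48 h, 87 at 8 d, 39 at 15 d. With both, each of 42 gene and 12 list results was on the same side of the threshold, so the pairing changed no other call among those named.

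Without the arrays of rats 18 and 53 the counts were tumour BB against untreated 193 at 48 h, contralateral MRT against untreated 1214 at 48 h, 1852 at 8 d, contralateral BB against untreated 501 at 48 h, 1721 at 8 d, contralateral MRT against BB 1966 at 6 h, 542 at 48 h, 801 at 8 d, 1626 at 15 d, contralateral MRT against BB, change to 8 d 244, the MRT effect between tissues 41 at 48 h and MRT against BB between tissues 855 at 6 h, 11 at 8 d, 42 at 15 d, and 4 gene results were lost. With the neuron markers as a covariate they were tumour MRT against untreated 362 at 6 h, 552 at 48 h, 4078 at 8 d, tumour BB against untreated 1914 at 8 d, tumour MRT against BB 395 at 8 d, 746 at 15 d, tumour MRT against BB, change to 8 d 1301, untreated tumour 8 d against 6 h 233 and tumour BB 15 d against 8 d 412. That covariate ended 17 of 233 gene and 11 of 58 list results, called 1 more list, and turned 5. By construction the neuron medians at 8 d went from 1.57 to -0.015 after MRT and from 0.91 to -0.23 after BB. In BB tumours at 8 d the mitosis median went from -0.72 to 0.12 and that of myelin genes from 1.10 to -0.023, and Tac1 between untreated tumours from -3.09 to 0.74. The Gapdh difference as a covariate gave tumour BB against untreated 128 at 48 h, tumour MRT against BB 265 at 15 d, tumour BB 15 d against 8 d 155, contralateral BB against untreated 2025 at 6 h, 203 at 8 d and contralateral MRT against BB 124 at 6 h, with 18 of 397 gene and 1 of 97 list results lost. Without the contralateral arrays of rats 30, 57, 59 and 60 the counts were contralateral BB against untreated 79 at 8 d and contralateral MRT against BB 325 at 15 d, with 15 of 164 gene results lost.

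Single arrays were left out only in groups of 5 or fewer, so no MRT array before 15 d and no BB array at 6 h was; the counts were tumour MRT against untreated 131 to 237 at 6 h, 107 to 261 at 48 h, tumour BB against untreated 75 to 297 at 48 h, 1576 to 4912 at 8 d, tumour MRT against BB 0 to 1459 at 8 d, 145 to 424 at 15 d, tumour MRT 15 d against 8 d 2155 to 4129, tumour MRT against BB, change to 8 d 208 to 1466, tumour BB 15 d against 8 d 77 to 1265, contralateral BB against untreated 1881 to 3222 at 6 h, 501 to 5151 at 48 h, 227 to 944 at 8 d, contralateral MRT against untreated 1214 to 5981 at 48 h, 735 to 1006 at 8 d, contralateral MRT against BB 93 to 161 at 48 h, 163 to 450 at 8 d, 342 to 846 at 15 d, contralateral MRT against BB, change to 8 d 60 to 145, the MRT effect between tissues 45 to 1451 at 48 h and MRT against BB between tissues 0 to 1 at 48 h, 0 to 344 at 8 d, 1 to 21 at 15 d. Of 2590 gene results so obtained 217 lost the call, and of 704 list results 16, and none turned.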

Other observations

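Lists in this part were fixed beforehand but taken up only after their results were seen. Brackets hold the median and the count adjusted over the list alone. Beside T cells and macrophages, MRT tumours at 8 d had more transcripts of other cell types than untreated ones. Astrocyte markers were higher in 10 of 13 (1.52, 10) and myelin genes in 11 of 13 (1.53, 11). B and plasma cell genes rose in 8 of 10 (1.13, 8). Astrocyte means were 9.89 to 11.15 after MRT, 8.67 to 10.01 untreated and 9.97 to 11.02 untreated at 6 h. So MRT tumours lay near the untreated 6 h level, as they did for myelin genes. Genes of homologous recombination and Fanconi repair fell in 9 of 16 (-0.88, 9), and angiogenic tip endothelium genes in 7 of 12 (-1.12, 7). At 8 d after BB, 4 of 13 astrocyte markers (1.00, 8) and 3 of 13 myelin genes (1.10, 4) were higher. With the neuron covariate the myelin median was -0.023. Of 12 tip endothelium genes 6 fell (-0.58, 6).

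In contralateral tissue, 7 of 12 markers of oligodendrocyte precursors fell at 48 h after MRT (-0.48, 7). At 8 d 4 of 12 fell (-0.33, 5), and 5 of 12 after BB (-0.26, 5). At 8 d, choroid plexus and ependyma genes were higher in 4 of 11 after MRT (1.01, 7) and 6 of 11 after BB (1.45, 9). Means were 7.71 to 8.82 after BB, 5.90 to 7.48 untreated and 5.95 to 8.45 untreated at 6 h, so low controls may contribute. How much of these tissues each sample holds was not tested. No list in this part held its call with an estimated correlation.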
